A study of Mus musculus with 30 samples.

How the data were processed

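Lungs and spleens of 8-week-old wild type, lincRNA-Cox2 mutant and lincRNA-Cox2 knockout mice were profiled 6 h after LPS (20 mg/kg) or with PBS, per the labels, in 30 libraries: 3 LPS and 2 PBS libraries per genotype and tissue. RNA was prepared with mRNA isolation kits, per the labels' protocols. The labels do not say that replicates are separate animals, nor which lung and spleen come from 1 mouse, and they give no batch.

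One table per tissue was used. STAR 2.5.3a, Bowtie2, SAMtools, bedtools and DESeq2 are named, with the mm10 genome, in the submitters' processing notes, without their order or settings. Per the file headers, each deposited table gives for every gene the mean over all libraries and 6 group means, a normalized signal that the notes' DESeq2 makes by dividing counts by size factors. For each of 6 genotype comparisons per tissue it gives a log2 fold change, an adjusted p-value that is treated as a score of the authors' deposited table, and a mark for calls. The authors' calls end at an adjusted p of 0.1 in the deposited tables: the largest called value was 0.1 in lung and 0.0999 in spleen, and the smallest value not called 0.100134 and 0.100741. The authors' deposited log2 folds are pulled towards 0, in the median most for low means. In mutant against wild type lung under LPS the median ratio of the fold to the log2 ratio of the means was 0.623 for genes with means of 1 to 10 and 0.959 above 200. Single genes with a high mean in 1 group can be pulled strongly too. For Mup20, knockout over mutant lung under LPS, the fold was 3.25 against 6.12 from group means with a pseudocount of 1. Per-library values were not used here, nor unadjusted p-values.

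For lung 19476 lines were read, of which 6 had broken cells and were left out, and for spleen 18850, of which 5 were left out. In spleen 1026 symbols had been split at a fixed width, with the end running into the next column, and were rejoined. Symbols turned into dates by a spreadsheet (25 in lung and 24 in spleen) were kept unnamed. Repeated symbols (242 and 241) were kept as separate entries, so 1 gene can be counted more than once; reads of near-identical copies such as histone and immunoglobulin genes cannot be assigned with certainty. The group means weighted by their libraries gave the overall mean within ratios of 0.994 to 1.01. Positions came from GENCODE M21 and, for older symbols, from synonyms of the RefSeq annotation of the same assembly (93.4% of lung and 93.6% of spleen entries). LincRNA-Cox2 is listed in GENCODE as Ptgs2os2. The counting is not stated to use strand, so antisense pairs cannot be told apart.

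Library depth was estimated from the smallest steps between low group means, since 1 read in 1 library adds a fixed amount. A group was accepted when at least 98% of its low values were whole combinations of steps within 0.5%; 6 lung and 5 spleen groups passed, with size factors of 0.501 to 2.33 and 0.521 to 2.51. The step finder recovered both steps in 10 of 10 groups of 2 libraries simulated from the lung means of 19470 entries. The floor for a group at 0 is 3 reads over the group, and covers counting error only.

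The design written before the data were examined called for fits on single libraries; with group means only, the authors' comparisons were used in place of these, at the planned threshold of an adjusted p under 0.05. LPS was compared with PBS as the log2 ratio of group means with a pseudocount of 1, in genes with a mean of at least 10 in either group. A ratio of at least 2-fold counted as a response, and a difference of responses of at least 1 (log2) was counted; both limits were chosen after seeing the data. For 46 gene lists written before the data were examined, the median log2 fold was placed among 10000 random lists of the same size, drawn from 100 neighbours on each side in mean expression. Genes of a list vary together, so a percentile describes these libraries and is no test: between 15 and 32 of 46 lists lay outside the central 95% in a comparison, against 2.3 by chance alone. Set tests and counts adjusted over the list alone need unadjusted p-values or libraries and were not run. On simulated values for lung, 3% of random lists lay outside the central 95%, and 80% of lists of 15 genes moved by 1 SD lay above it.

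Called genes with distinct symbols and a position were compared between chromosomes by Fisher's exact test, two-sided, adjusted by Benjamini-Hochberg over chromosomes, with all tested genes of known position as background. Signs of folds were compared between tissues by a two-sided binomial test. In simulations 4% of permuted call sets had a chromosome past the threshold and 100% of sets with 20 planted calls were found. For shared calls the number for independent lists and a simulation of unchanged groups against the same controls were computed.

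The text names lincRNA-Cox2 and Ptgs2 in every group, the 6 largest rises and 6 largest falls per comparison at an adjusted p under 0.05 with a mean of at least 50 in the higher group, up to 4 members of a list with the smallest adjusted p, the sex-linked genes and neighbours of the locus. Of these only some are printed. The rule's demand that libraries of the groups not overlap could not be applied, and the LPS response was ranked without a test. Genes named outside the rule are said to be chosen after their values were seen; this holds also for Slc25a37, Igj, Wdfy1, Hbegf and the genes on chromosome 1.

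Alternatives were a pseudocount of 10, no filter on low values, group means rescaled by a trimmed mean of ratios, an adjusted p up to 0.1, a higher group mean of at least 10, ratios of group means in place of the authors' folds, and counts without chromosome 1 or without X and Y. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 with seed 7.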

Results

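Messenger RNA was sequenced from lungs and spleens of 8-week-old C57BL/6 mice of 3 genotypes: wild type, a line labelled lincRNA-Cox2 mutant and a line labelled lincRNA-Cox2 knockout. LincRNA-Cox2 is a long noncoding RNA transcribed next to Ptgs2, the gene of cyclooxygenase 2, and the comparison of the 2 lines asks which genes depend on the RNA and which on its locus. Mice were injected intraperitoneally with lipopolysaccharide (LPS, a bacterial cell wall component that activates Toll-like receptor 4) at 20 mg/kg and tissues were taken after 6 h; the controls are labelled PBS. Each tissue had 15 libraries, 3 per genotype with LPS and 2 per genotype with PBS, and the labels do not say whether the lung and spleen libraries came from the same animals. The values are the authors' group means of normalized counts and the folds and adjusted p-values of the authors' deposited table, so no spread between replicates is given. Estimated library totals ran from 5.20 to 17.3 M reads in lung and from 2.38 to 8.95 M in the 5 spleen groups that could be resolved. A gene is called here at an adjusted p under 0.05.

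The targeted RNA was lost from both lines in lung. In wild type lung the authors' mean of lincRNA-Cox2 was 30.2 normalized counts with LPS and 34.8 with PBS, and it was 0 in mutant and knockout lungs under both treatments. Against a floor of 3 reads over the group, expression was at least 24.7-fold lower in the mutant and at least 15.1-fold lower in the knockout with LPS, and at least 23.5-fold and 33.5-fold lower with PBS; these floors cover counting error only. The log2 fold of lincRNA-Cox2 was -4.77 in the mutant with an adjusted p of 1.67e-06 and -4.58 in the knockout with an adjusted p of 2.09e-06 under LPS in the authors' deposited table. In spleen the authors' mean was 3.53 in wild type with LPS, 2.13 with PBS, 0.322 in the knockout with LPS and 0 in the other groups. Against the same floor the knockout with PBS was at least 1.59-fold lower than wild type, while the floor of the mutant with PBS, 2.33, lay above the wild type mean and no floor was computed for LPS.

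Ptgs2, which makes prostaglandin precursors at sites of inflammation, separated the 2 lines. It lies 50.8 kb from lincRNA-Cox2 on chromosome 1 (mm10; Ptgs2 at 150100031 to 150108227, lincRNA-Cox2 at 150159043 to 150164948). With LPS the authors' mean of Ptgs2 in lung was 1397 in wild type, 1058 in the mutant and 208 in the knockout, and with PBS it was 189, 154 and 23.4. Ptgs2 fell by 2.70 (log2) in the knockout against wild type under LPS, adjusted p 3.64e-31, and by 2.88 under PBS, adjusted p 1.66e-17, in the authors' deposited table. The mutant differed from wild type by -0.39 under LPS, adjusted p 0.972, and by -0.27 under PBS, adjusted p 1, per the authors' deposited table. Knockout and mutant themselves differed by -2.31 under LPS, adjusted p 6.63e-22, and by -2.60 under PBS, adjusted p 9.62e-14, in the authors' deposited table. The log2 ratio of the authors' LPS mean to the PBS mean for Ptgs2 was 2.88 in wild type, 2.77 in the mutant and 3.10 in the knockout. In spleen, where the authors' LPS means of Ptgs2 were 214, 111 and 65.8, neither line was called against wild type; the knockout stood at -1.41 with an adjusted p of 0.566 in the authors' deposited table.

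Pla2g4a, the cytosolic phospholipase that releases arachidonic acid for Ptgs2 and its neighbour at 149829618 to 149961290, fell in knockout lung under LPS by 0.97 with an adjusted p of 0.00136 in the authors' deposited table. Its authors' mean was 275 in wild type, 249 in the mutant and 138 in the knockout. Ptgs2os, an antisense gene that starts beside Ptgs2, had an authors' mean of at most 5.20 in any lung group. The 11 genes listed beforehand as neighbours of the locus had a median log2 fold of 0.00 in the knockout under LPS, with these 2, Ptgs2 and Pla2g4a, called lower. Of the 21 measured genes of prostaglandin synthesis and its receptors the same 2 were called in the knockout, and none in the mutant.

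**Figure D1:**
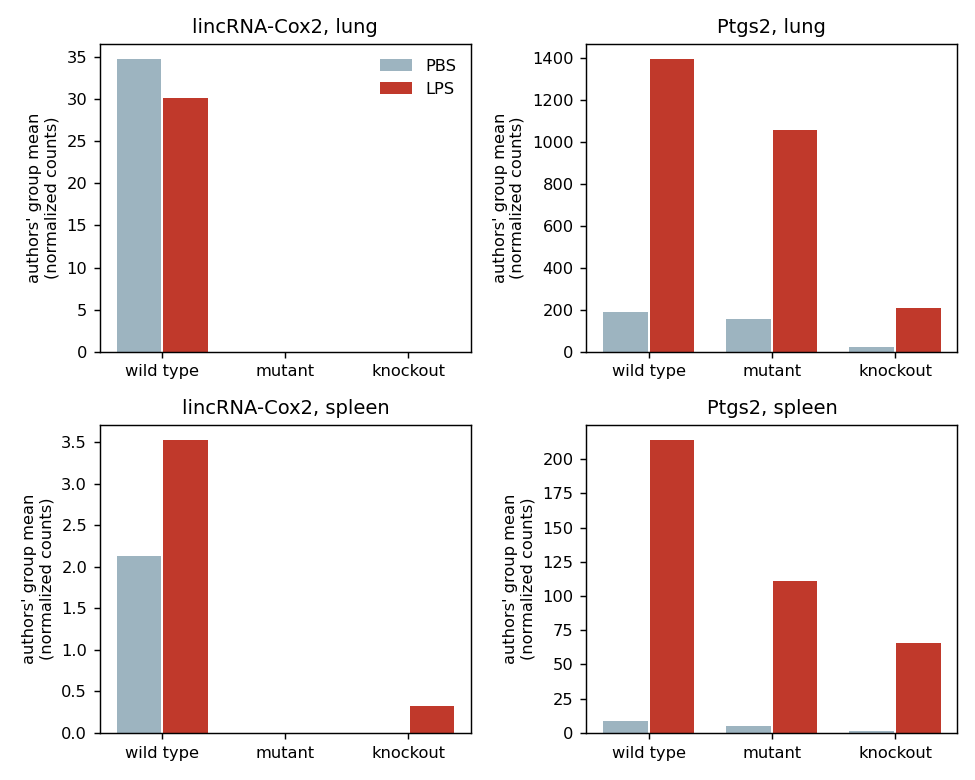
LincRNA-Cox2 and Ptgs2 in lung (top) and spleen (bottom). Bars are the authors' group means of normalized counts for PBS (2 libraries) and LPS (3 libraries); no error bars are drawn because per-library values were not used here. LincRNA-Cox2 is at 0 in mutant and knockout lung, while Ptgs2 with LPS is 1058 in the mutant and 208 in the knockout.

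LPS against PBS in wild type mice sets the background for the genotypes. In lung the authors' mean of Cxcl11, a chemokine of activated T cells, was 5.09 with PBS and 2050 with LPS. That of Csf3, a growth factor of neutrophils, was 2.48 and 1060, and that of Cxcl2, a chemokine of neutrophils, 14.2 and 3060. Adamts4, a protease of the extracellular matrix, went from 7.27 to 1870, and Ubd, a ubiquitin-like modifier, from 3.63 to 991. Xist, expressed from the inactive X chromosome in females, had the lowest ratio among named genes, with authors' means of 3660 with PBS and 14.5 with LPS, followed by Glp1r, the glucagon-like peptide 1 receptor, at 219 and 2.99. In spleen Ifng, the main activator of macrophages, had an authors' mean of 11.8 with PBS and 1700 with LPS, and Il6 went from 7.42 to 747; Xist went from 2470 to 31.3 and Xcr1, a receptor of cross-presenting dendritic cells, from 127 to 2.25. The LPS and PBS groups thus differed in sex-linked expression in wild type, so treatment and sex are confounded in these ratios and in the differences of responses between genotypes.

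Gene lists fixed beforehand gave the same picture. In wild type lung 21 of 23 inflammatory cytokines and 35 of 38 type I interferon response genes were at least 2-fold higher with LPS, with median log2 ratios of 3.79 and 2.91. The 29 chemokines had a median of 4.19, and the 10 markers of immature neutrophils a median of 5.07. Endothelial markers had a median of -2.07 in lung, with 10 of 15 at least 2-fold lower. In spleen the medians were lower for cytokines (1.89) and type I interferon genes (2.11), while B cell and T cell markers stood at -0.56 and -0.41. In total 4256 of 15041 lung genes and 3832 of 13513 spleen genes differed at least 2-fold in wild type. The authors' deposited table holds no test of LPS against PBS, so these are ratios of means without a p-value, and the 2-fold limit was chosen after the data were seen.

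The response in both lines resembled that of wild type in lung. The log2 LPS ratios correlated across genes between wild type and mutant lung with r = 0.937, and between wild type and knockout lung with r = 0.920; genes are not independent replicates. In spleen both correlations with wild type were lower, 0.755 and 0.755, against 0.901 between mutant and knockout. Type I interferon response genes had larger LPS ratios in both lines than in wild type, with medians of 4.06 and 3.89 in mutant and knockout lung and 3.57 and 3.42 in spleen. That difference came with a higher starting level in the wild type PBS groups, described with the PBS comparisons. Markers of organs other than the sampled organ varied between groups too: hepatocyte markers had a median log2 LPS ratio of -2.02 in wild type spleen but 5.46 in the mutant, where the authors' mean of Alb (albumin) was 8.27 with PBS and 1570 with LPS. Markers of pancreatic acinar cells had medians of 3.85, 0.22 and 1.74 in wild type, mutant and knockout spleen.

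**Figure D2:**
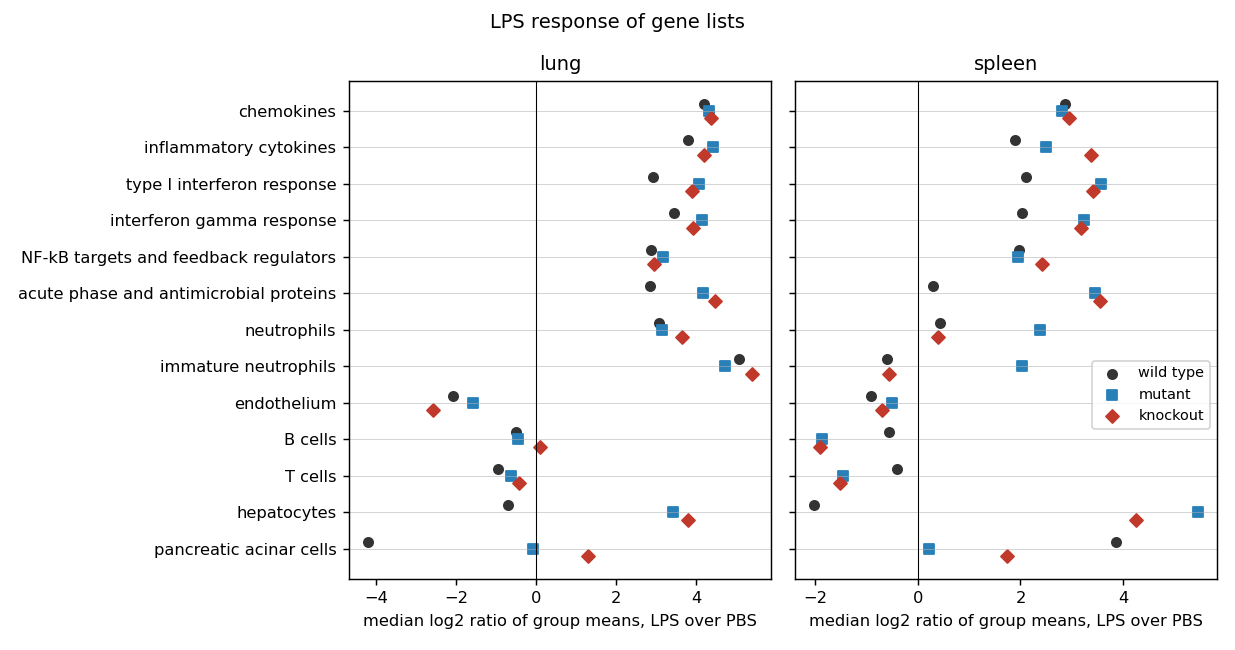
Median log2 ratio of the authors' group means, LPS over PBS, for 13 gene lists in lung (left) and spleen (right). Each marker is 1 genotype. In wild type lung the chemokine median is 4.19 and the endothelial median -2.07; hepatocyte markers in spleen range from -2.02 in wild type to 5.46 in the mutant.

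The mutant against wild type under LPS asks what losing the RNA does while Ptgs2 stays near its normal level. In lung Mid1, an X-linked ubiquitin ligase that binds microtubules, rose from an authors' mean of 407 to 2019, a log2 fold of 2.19 with an adjusted p of 2.41e-05 in the authors' deposited table. Zbtb32, a transcriptional repressor in lymphocytes, rose by 1.51, adjusted p 0.00575, and Eif4ebp3, which binds the cap-binding factor of translation, rose by 1.06, adjusted p 0.0364, in the authors' deposited table. Ide, the insulin-degrading enzyme, fell by 0.90, adjusted p 0.0154, and the pseudogene Tmem181b-ps fell by 1.19, adjusted p 1.3e-05, in the authors' deposited table. One of 2 entries for Slc25a37, the mitochondrial iron importer mitoferrin, fell by 2.97, adjusted p 1.3e-05, in the authors' deposited table; it is named because of its value.

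In total 12 of 16774 tested entries were called in mutant lung, 7 higher and 5 lower. None of the 27 NF-kB targets and feedback regulators, 29 chemokines or 23 inflammatory cytokines was called in the mutant. Their median log2 folds were 0.26, 0.20 and 0.05, at percentiles 100, 99.9 and 65.5 of random lists matched on expression. Cell cycle genes had a median of -0.45 with 24 of 26 below 0 and none called. The mutant LPS lungs also differed in sex-linked genes. The authors' mean of Xist was 4510 there but 14.5 in wild type and 23.2 in the knockout, and the Y-linked Ddx3y was at 4.73 against 1150 and 1130. All PBS groups carried both, with Xist from 1910 to 3660 and Ddx3y from 294 to 447. Xist was not called between mutant and wild type, with a log2 fold of 2.11 and an adjusted p of 0.92 in the authors' deposited table. That fold is pulled towards 0, as the means of 4510 and 14.5 show, and does not stand for a small difference.

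**Figure D3:**
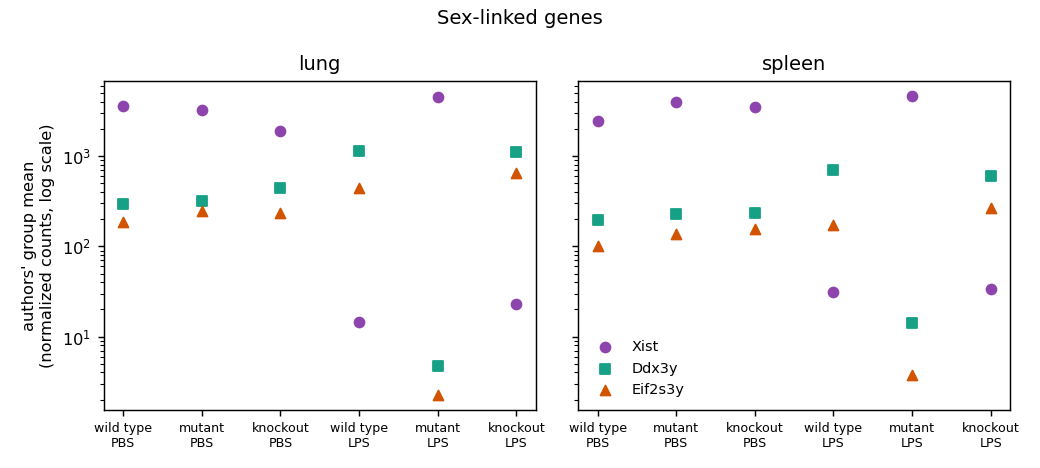
Authors' group means of Xist and of the Y-linked genes Ddx3y and Eif2s3y on a log axis, by genotype and treatment, in lung (left) and spleen (right). In the mutant LPS groups Xist is at 4510 in lung and 4670 in spleen, and Ddx3y at 4.73 and 14.0; the wild type and knockout LPS groups show the reverse, and the PBS groups hold both.

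The knockout against wild type under LPS adds the loss of most Ptgs2 expression. In knockout lung Hist1h2af, a replication-dependent histone gene, rose by 2.91 with an adjusted p of 4.43e-06, and Ctse, the aspartic protease cathepsin E, by 2.69 with an adjusted p of 1.45e-06, in the authors' deposited table. With PBS the authors' means of Hist1h2af were 10.9 in wild type and 8.9 in the knockout. Cell cycle genes had median log2 LPS ratios of 1.26 in wild type and 1.28 in knockout lung. Differences between libraries in what the mRNA kits captured cannot be seen from group means, and the cause of the Hist1h2af rise was not tested. Tnn, an extracellular matrix glycoprotein, rose by 2.02, adjusted p 9.59e-06, and Steap3, an endosomal iron reductase, by 1.60, adjusted p 1.45e-06, in the authors' deposited table. Mcm6, a subunit of the replicative helicase, fell by 1.11, adjusted p 4.98e-04, and Nnt, a mitochondrial transhydrogenase that makes NADPH, fell by 1.01, adjusted p 0.0208, in the authors' deposited table. Lox, which crosslinks collagen and elastin, fell by 0.87, adjusted p 0.00301, in the authors' deposited table, and is named after its value was seen.

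All 12 B cell markers were above 0 in knockout lung, with a median log2 fold of 1.00 at percentile 100 of random lists. Pax5, the transcription factor of B cell identity, was the 1 marker called, rising by 1.62 with an adjusted p of 0.00517 in the authors' deposited table. Ms4a1, a B cell surface protein, had authors' means of 94.6 and 218 and was not called. Immunoglobulin entries went with them. Ighg, an immunoglobulin heavy chain entry, rose by 1.83, adjusted p 0.00244, and Igj, the joining chain of secreted antibodies, by 1.21, adjusted p 0.0178, in the authors' deposited table. T cell markers had a median of 0.14 at percentile 85.8. Endothelial markers had a median of -0.51 with 10 of 15 below 0, and none was called; Kdr, a receptor of vascular endothelial growth factor, stood at -1.07 with an adjusted p of 0.099 in the authors' deposited table.

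Cytokine genes of knockout lung lay near wild type, with a median of -0.01 and none of 23 called; Tnf stood at -0.70 with an adjusted p of 0.303 in the authors' deposited table. Chemokines had a median of 0.35 with none of 29 called. In total 69 of 15656 entries were called, 47 higher and 22 lower, and 121 at an adjusted p up to 0.1. Markers of other organs were higher in the knockout LPS lungs: hepatocyte markers had a median log2 fold of 1.40, skeletal muscle markers 1.54 and pancreatic acinar markers 1.21, with none called. The authors' mean of Alb was 2460 there and 242 in wild type, and that of Acta1, skeletal muscle actin, was 157 and 2.01.

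The knockout against the mutant under LPS sets the 2 lines side by side. Apart from Ptgs2, Dio2, which activates thyroid hormone, fell by 1.73 with an adjusted p of 0.00166, and Mmp2, a gelatinase of stromal cells, by 1.33 with an adjusted p of 0.0332, in the authors' deposited table. Ctse rose by 2.93, adjusted p 5.4e-08, and Hist1h1e, a linker histone, by 2.40, adjusted p 0.00192, in the authors' deposited table. Of 26 cell cycle genes 23 were above 0, with a median of 0.57; the proliferation marker Mki67 rose by 1.19, adjusted p 0.0136, and Mcm6 fell by 1.30, adjusted p 4.41e-06, in the authors' deposited table. In total 39 of 16030 entries were called, 22 higher and 17 lower, and 82 at an adjusted p up to 0.1. These groups differ in Xist and the Y-linked genes as given above, with authors' means of Xist of 4510 and 23.2.

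Without LPS few genes separated the genotypes in lung. In the knockout against wild type 8 of 18982 entries were called: Tnn rose by 3.15, adjusted p 7.62e-12, Ctse by 3.06, adjusted p 1.4e-05, and Cebpd, a transcription factor of the acute phase response, by 1.02, adjusted p 2.58e-04, in the authors' deposited table. Chil1, a chitinase-like protein of macrophages and epithelium, fell by 2.95 with an adjusted p of 4.31e-20 in the authors' deposited table, from an authors' mean of 5256 to 635. With LPS the authors' means of Chil1 were 14207 and 12247, and it was not called, adjusted p 0.848, in the authors' deposited table. Skeletal muscle markers had a median log2 fold of 2.55 in the knockout PBS lungs, with an authors' mean of Acta1 of 1100 against 2.04 in wild type. In the mutant against wild type only lincRNA-Cox2 was called. Between knockout and mutant 10 entries were called, among them Wdfy1, an endosomal adaptor, which fell by 1.10 with an adjusted p of 3.14e-06 in the authors' deposited table.

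Genes called in knockout lung lay on chromosome 1 more often than tested genes did. Under PBS, 7 of 8 called genes of known position were on chromosome 1, which held 6.01% of tested genes (Fisher's exact test, two-sided, adjusted p 4.41e-07 over chromosomes). Besides lincRNA-Cox2 and Ptgs2 these were Steap3 (starting at 120 Mb), Mcm6 (128 Mb), Ctse (132 Mb), Chil1 (134 Mb) and Tnn (160 Mb). Without the 1 Mb on either side of lincRNA-Cox2 the count was 5 of 6 (adjusted p 8.95e-05). Under LPS 11 of 56 were on chromosome 1 (adjusted p 0.00772), and 8 of 53 without that interval (adjusted p 0.242); for calls at an adjusted p up to 0.1 it was 14 of 100 without that interval (adjusted p 0.0431). In mutant lung under LPS the count was 1 of 9, the targeted RNA itself. In knockout spleen against wild type it was 2 of 2 under LPS, Ctla4 and Tnnt2 (adjusted p 0.0736), and 0 of 5 under PBS (adjusted p 1). With 2 calls, both on chromosome 1, no smaller adjusted p could be reached, so the spleen test under LPS could not decide. The spleen test under PBS could not decide for these 2 genes either. Only 3124 spleen entries had an adjusted p there, and Ctla4 (log2 fold 0.07) and Tnnt2 (-2.18) had none. Chromosome 1 was the only chromosome past the threshold in these tests, which were chosen after the calls were seen.

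**Figure D4:**
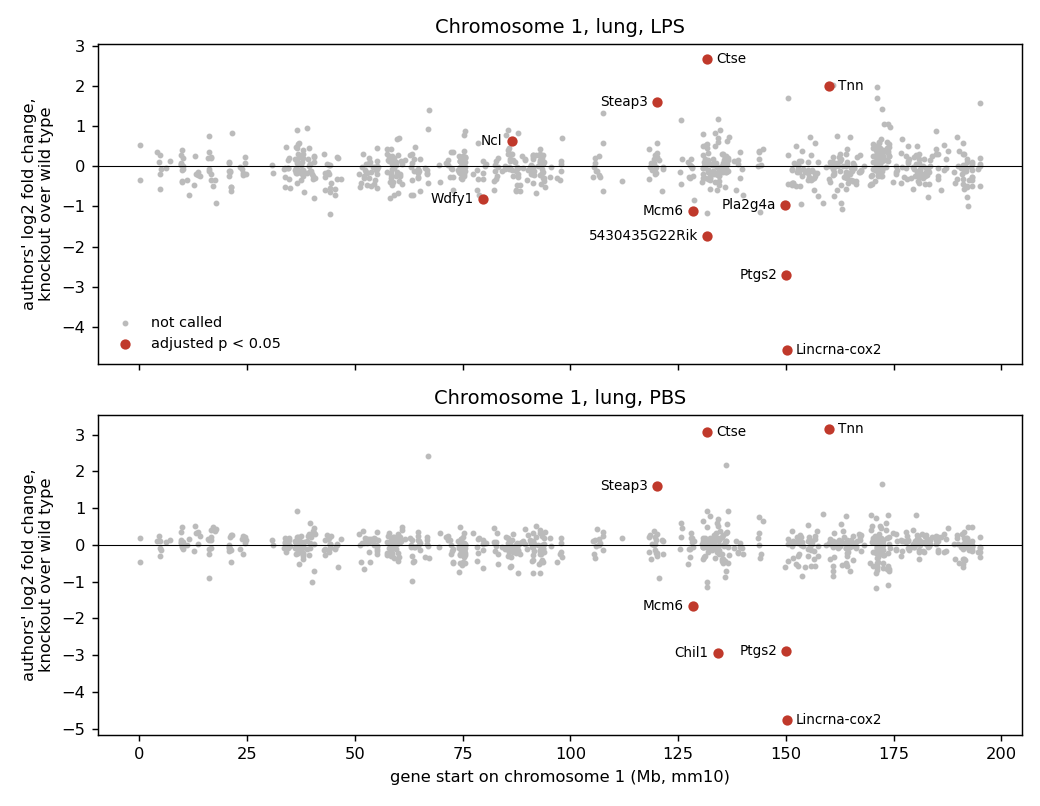
Log2 fold changes of knockout over wild type lung along chromosome 1 with LPS (top) and PBS (bottom), from the authors' deposited table. Points are genes with a mean over all libraries of at least 10; red points have an adjusted p under 0.05 and carry their symbols, and they spread from Steap3 at 120 Mb to Tnn at 160 Mb in the PBS panel.

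The 2 lines shared 5 lung calls against wild type under LPS. Zbtb32, Eif4ebp3 and an immunoglobulin entry were higher in both, against 0.0210 expected of independent lists. LincRNA-Cox2 and Tmem181b-ps were lower in both, against 0.00703. No gene was called in opposite directions. Both comparisons use the same 3 wild type libraries, so part of this excess may come from the shared controls. Across 11942 genes the covariance of the folds was 0.0398, and simulated unchanged groups against shared controls gave 0.0403. The simulated value follows from the spread given to the unchanged groups, so it cannot decide how much of the overlap comes from shared controls.

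In spleen under LPS fewer entries were called against wild type, 1 in the mutant and 4 in the knockout, than the 21 between the lines. Ctla4, an inhibitory receptor of T cells, rose in the knockout under LPS by 1.53 with an adjusted p of 0.0159, and Tnnt2, a troponin of heart muscle, fell by 1.68 with an adjusted p of 0.0159, in the authors' deposited table. These and 2 immunoglobulin entries were the 4 calls among 16572 entries tested; 22 were called at an adjusted p up to 0.1. In the mutant Mid1 was the 1 call, rising by 2.99 with an adjusted p of 8.45e-06 in the authors' deposited table; with PBS its authors' means were 58.2 in wild type and 464 in the mutant. Mid1 lies on the X chromosome, and the mutant LPS spleens had an authors' mean of Xist of 4670 against 31.3 in wild type.

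Neutrophil granule genes separated knockout from mutant spleen. Elane, neutrophil elastase, fell by 2.55 with an adjusted p of 0.00411, Ltf, lactoferrin, by 2.52 with an adjusted p of 0.0108, and Prtn3, proteinase 3, by 2.39 with an adjusted p of 0.0342, in the authors' deposited table. All 10 markers of immature neutrophils were below 0, with a median of -2.31, and 4 were called. Against wild type the same list had a median of 1.79 in the mutant and -0.54 in the knockout, with no member called in either; the authors' mean of Elane was 83.8, 408 and 50.6 in wild type, mutant and knockout. The mutant and knockout LPS spleens also differed in sex-linked genes, with authors' means of Xist of 4670 and 33.7 and of Ddx3y of 14.0 and 601, so sex and genotype are confounded here. Fosl1, a subunit of the AP-1 transcription factor, rose by 2.19, adjusted p 0.0342, and Hbegf, an epidermal growth factor receptor ligand, by 1.61, adjusted p 0.0119, in the authors' deposited table. In total 21 of 11871 entries were called, 5 higher and 16 lower.

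Inflammatory cytokines lay higher in knockout spleen under LPS without passing the test. Of 23 genes 22 were above 0 against wild type, with a median of 0.74 at percentile 100, and the chemokine median was 0.72. Ifng had authors' means of 1700 in wild type, 1380 in the mutant and 4690 in the knockout, and stood at 1.27 in the knockout with an adjusted p of 0.588 in the authors' deposited table. B cell markers had a median of -0.49 and plasma cell markers 0.84 in the knockout against wild type.

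With PBS the calls in spleen were interferon response genes and a protease. In knockout spleen Ifi44 fell by 2.01, Ifit1 by 1.88 and Irf7, a transcription factor of the interferon response, by 1.86, each with an adjusted p of 0.0295 in the authors' deposited table. Slfn4 fell by 2.45 and Mmp3, a matrix protease, by 2.02 at the same adjusted p of 0.0295 in the authors' deposited table, and these 5 were all the calls among 3124 entries tested. Type I interferon response genes had a median of -0.99 in knockout and -0.86 in mutant spleen, with 37 of 37 below 0 in each. In lung the medians were -0.76 and -0.81 with 37 of 38 below 0, and none was called. The mutant had 0 calls against wild type in spleen under PBS among 18357 entries tested, by the authors' DESeq2 test. The knockout had 0 against the mutant among 18185. The numbers tested were so unequal that 5 calls against 0 do not show a difference between the lines. Both lines were set against the same 2 wild type PBS libraries. Unadjusted p-values were not analysed here.

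The difference of the LPS responses between genotypes has no test in the authors' deposited table, and is given as counts. The log2 fold between genotypes under LPS minus that under PBS was 1 or more in size for 587 lung genes in the mutant and 886 in the knockout. Other settings moved the lung counts by more than 1.5 times, to between 288 and 1103 in the mutant and between 532 and 1471 in the knockout. In spleen the counts were 1180 and 1984. Both share the wild type PBS groups, whose type I interferon genes stood high.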

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

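The tests weighed in this part were all chosen after the results were seen. The 2 lines differed from each other where a shared loss of lincRNA-Cox2 would leave them alike: 39 lung entries under LPS, 10 lung entries under PBS and 21 spleen entries under LPS were called between knockout and mutant. Ptgs2 in lung was lower in the knockout than in the mutant by log2 folds of -2.31 under LPS and -2.60 under PBS in the authors' deposited table.

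The first pattern is the concentration of knockout calls on chromosome 1 in lung, among them Ctse, Tnn, Steap3, Mcm6, Chil1 and Ptgs2. Under PBS a chance distribution of calls over chromosomes (adjusted p 4.41e-07) and a local effect within 1 Mb of lincRNA-Cox2 as the whole cause (adjusted p 8.95e-05 without that interval) are argued against. Under LPS a local effect and a wider cause of the excess cannot be told apart, since the excess without that interval depended on the limit for calls (adjusted p 0.242 at 0.05 and 0.0431 at 0.1 against wild type, 0.0643 and 0.224 against the mutant). Of the 10 other genes called on chromosome 1 under LPS, 7 were also called between knockout and mutant, which both lack the lincRNA-Cox2 transcript. Loss of the transcript alone is argued against for Ptgs2, Tnn, Ctse, Steap3, Mcm6 and Wdfy1, which were called there with PBS as well. Pla2g4a was called there only under LPS, where these groups also differ in sex-linked genes, so for it this cannot be told apart. For the other 3 genes it cannot be told apart either, as all 3 had the knockout's sign in the mutant without a call. A candidate explanation for the 8 genes beyond 1 Mb is a chromosome 1 segment of another strain carried with the knockout allele. Of these, 6 kept their sign under PBS, while Ncl and C1ql2 changed it. Among the 6, Steap3, Mcm6, Ctse, 5430435G22Rik and Tnn start between 120 and 160 Mb, around lincRNA-Cox2 at 150 Mb. Wdfy1, at 79.7 Mb, widens the spread to 80.4 Mb. Chil1, at 134 Mb, was called against wild type under PBS only and is not among the 8. Its log2 fold was -2.95 under PBS and -0.21 under LPS in the authors' deposited table, so its difference did not stay at that size. A lasting effect of the deletion would keep signs too, so these explanations cannot be told apart without genotypes of the mice.

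The second pattern is the sex-linked expression of the mutant LPS groups, with authors' means of Xist of 4510 in lung and 4670 in spleen against 14.5 and 31.3 in wild type. In lung, exchanged labels of the mutant and another LPS group are argued against. An exchange with wild type would put lincRNA-Cox2 above 0 in the group labelled mutant, where it was at 0. An exchange with the knockout would turn the sign of Ptgs2 between these LPS groups. Ptgs2 was lower in the group labelled knockout under LPS (log2 fold -2.31, adjusted p 6.63e-22 in the authors' deposited table), as it was with PBS (-2.60). In spleen 8 of the 10 entries called between knockout and mutant lung with PBS kept their sign under LPS (sign test, two-sided, p 0.109). Nnt, Wdfy1, Ide, Entpd4 and Slc25a37, in the entries compared at the end of the text, had 1 sign between knockout and mutant spleen under both treatments (Nnt -1.08 with LPS and -0.71 with PBS). These genes were picked from lung calls and no spread between libraries is given, so an exchange in spleen cannot be told apart. Sex of the mice is argued against for lincRNA-Cox2, called between mutant and wild type lungs with PBS too (adjusted p 3.9e-06 in the authors' deposited table), where Xist and Ddx3y were similar. For the other 11 mutant lung calls under LPS sex and genotype cannot be told apart. Of these, 4 were also called in the knockout, whose Xist and Ddx3y match wild type, but both calls use the same wild type libraries. The covariance of the folds (0.0398) did not exceed that of simulated unchanged groups (0.0403). That simulated value follows from the spread given to the simulation, so it cannot decide. Of the 7 not shared with the knockout 6 kept their sign with PBS and none was called; Mid1 stood at 1.15 in lung and 2.38 in spleen and Ide at -0.59 and -0.62 in the authors' deposited table.

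The third pattern is the B cell marker expression of knockout lung under LPS, with Pax5 called and all 12 markers above 0. Lymphoid tissue carried into these libraries may raise B cell genes, and tissue holding T cells would raise their genes as well. The B cell median exceeded the T cell median by 0.86, more than the interquartile range of 0.32 of the T cell markers. That range describes genes and not libraries, and tissue rich in B cells would give the same gap, so carried tissue cannot be told apart. Hepatocyte, skeletal muscle and pancreatic acinar markers also stood higher in these libraries, as given above. B cell content raised in both models remains open: the B cell median of the mutant under LPS was 0.52, above the range of random lists, although the shared wild type libraries enter both values. Median log2 LPS ratios of the B cell markers in lung were -0.51 in wild type, -0.46 in the mutant and 0.10 in the knockout. The mutant thus stood close to wild type in its LPS ratio.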

How the results depend on the processing

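The alternatives added after seeing the data are the adjusted p up to 0.1, the higher group mean of at least 10, ratios with a pseudocount of 1, and the counts without chromosome 1 or without X and Y. No result reversed. At an adjusted p up to 0.1, by construction a wider limit, calls numbered 121 (from 69) in knockout against wild type lung under LPS, 82 (from 39) in knockout against mutant lung under LPS, 22 (from 4) and 44 (from 21) for the same comparisons in spleen, and 12 (from 5) in knockout against wild type spleen under PBS. Without genes on chromosome 1, where the calls lie, lung calls under PBS were 0 for mutant against wild type (from 1), 1 for knockout against wild type (from 8) and 3 for knockout against mutant (from 10), and 2 for knockout against wild type spleen under LPS (from 4). Without X and Y the only mutant call in spleen under LPS, Mid1, was gone, leaving 0. Differences of LPS responses in lung numbered 288 with ratios of means and a pseudocount of 10 and 1103 with no filter on low values for the mutant (from 587), and 532 and 1471 for the knockout (from 886); the cause was not tested. The other counts stayed within 1.5 times, among them all 10 under rescaling by a trimmed mean of ratios. All 54 folds of named genes under LPS kept their sign under each pseudocount. At a pseudocount of 1 and 10, 4 and 6 of these folds differed by more than 0.5 (log2). Folds and ratios rest on the same libraries, and most of these genes were named for large folds. The kept signs were therefore nearly fixed in advance and lend no support. Leaving out each replicate, fits of only the compared groups, array weights, a new DESeq2 fit, camera and fry need per-library values and were not run. For the same reason no other split of the libraries was drawn; 3 against 3 gives 10 splits. No paired analysis was possible because only group means were used. Depth limits lincRNA-Cox2 in spleen, where the authors' mean reached only 3.53.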

Other observations

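The hypothesis at the end of this part was tested only after its lung values had been seen. Markers of other organs varied between groups. Ctrb1, the pancreatic protease precursor chymotrypsinogen, had authors' means in spleen of 166 in wild type, 6390 in the mutant and 673 in the knockout with PBS, and of 5410, 7930 and 2200 with LPS. In lung it was at 190 in wild type with PBS and at 52.4 or less in the other groups. Myh1, a fast skeletal muscle myosin, was at 1030 in knockout lung with PBS and 188 with LPS, and at 1.73 or less in the other lung groups. Alb was at 855 in wild type spleen with PBS and at 8.27 in the mutant.

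Of 11 genes with an earlier reported link to lincRNA-Cox2 in macrophages, 11, 10 and 10 were at least 2-fold higher with LPS in wild type, mutant and knockout lung and 9 in spleen of each genotype, and 1 was at least 2-fold lower in mutant and in knockout spleen. Their median log2 ratio was 3.17, 3.74 and 4.26 in wild type, mutant and knockout lung, and 2.17, 3.63 and 3.29 in spleen. Between genotypes under LPS their medians were 0.10 in mutant and -0.06 in knockout lung, with no member called. Platelet and megakaryocyte markers had LPS medians of 2.18, 1.41 and 1.88 in lung, and neutrophil markers 3.07, 3.13 and 3.63. In spleen neutrophil markers had LPS medians of 0.44, 2.39 and 0.39.

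Nnt, Wdfy1, Ide, Entpd4 and Slc25a37 were each called between knockout and mutant lung under LPS. C57BL/6J mice carry a partial deletion of Nnt, and colonies of this strain differ in copies of the segment that holds Ide. A candidate explanation is variants that differ between breeding colonies of the lines. Of the other 15 folds of these 5 genes (lung with PBS and spleen with either treatment), all 15 kept the sign they had in lung under LPS. For Slc25a37 this is the called entry (3.70 in lung under LPS and 1.10 in spleen with PBS in the authors' deposited table). Its other, more abundant entry stood at 0.06 and -0.24 in the authors' deposited table. The called entry is numbered between entries of Entpd4, so the 15 folds may not come from separate loci. Wdfy1 is also among the chromosome 1 calls of the knockout. Stable effects of either allele would give the same, so the explanations cannot be told apart without genotypes of the mice.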
